A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

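The series held 25 two-colour arrays of budding yeast cells taken 3 h after transfer to sporulation medium, when meiotic DNA breaks form. Each array compared DNA immunoprecipitated (IP) with 1 of 6 targets against the input DNA of the same kind of culture. The targets were Hop1, Rec114, Mer2, Mre11, histone H3 trimethylated on lysine 4 (H3K4me3) and histone H3, each from wild-type cells and from pch2 mutant cells. The 12 groups held 2 arrays each, except Rec114 in wild type with 3, and the labels call the arrays of a group biological replicates. Per the labels, each IP used 25 ml of culture, and Rec114, Mer2 and Mre11 were precipitated through a Myc tag. No array of an untagged strain was among the samples, so the background of the Myc antibody was not measured.

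Per the file headers, the arrays of 60-mer probes were read with Agilent Feature Extraction 10.1.1.1, whose processed signals are intensity values, background-subtracted, detrended across the array and linearly dye-normalized within it. The deposited scanner files also held raw mean and local background signals, again as intensity, and marks for spot quality, which count here as other information. The headers name a ChIP extraction protocol for wild type replicate 1 of Mer2 and of Mre11 and a CGH protocol otherwise. Of 2 scanners, 1 read only Mer2 pch2 replicate 2, Mre11 wild type replicate 2 and both Mre11 pch2 arrays. Mre11 wild type replicate 2 and pch2 replicate 2 were scanned at 3 microns, the rest at 5. Protocol and scanner thus went in part with strain for Mer2 and Mre11. The authors also gave 1 table of log2 ratios with a column per array and a mean column per group. Its values were tested against the scanner files: column medians lay between -0.0336 and 0.00973, and each column had r of 0.659 to 0.965 with its own array. For 2 arrays, described below, r was positive only after they were turned to the direction of the table. For 4 of the 25 columns, which are all those of Hop1, the other replicate of the group matched better than the array with the same number. Whether the Hop1 replicate numbers are crossed between the table and the scanner files was not settled. The numbers of the scanner files are used here, and the columns were not used for single arrays except in 1 alternative fit. How the authors normalized their table is not given in the sources used here.

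For the main analysis log2(IP/input) was computed from the processed signals of 41418 probes, and each array was centred on the median of its nuclear probes. By the labelled dyes, 2 arrays ran against the others of their target. Rec114 wild type replicate 2 had r of -0.90 to -0.81 with the other 4 Rec114 arrays and -0.868 with its own column in the authors' table. Mer2 pch2 replicate 2 had r of -0.87 to -0.80 with the other 3 Mer2 arrays and -0.937 with its own column. The authors' direction was used for both, a departure from the plan to follow the labelled dyes. These negative r with every other array of the target argue against the labelled dyes for both arrays. No source outside the series was used to settle it. Gene calls, lists, location differences, chromosome trends, profile correlations, windows and differences between targets were also computed with the labelled dyes and without both arrays.

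Spots marked as non-uniform or as population outliers on any array of a target were left out for that target. Marks were not applied from 3 Mre11 arrays on which over 20% of spots carried them, wild type replicate 1 (69.8%), wild type replicate 2 (33.3%) and pch2 replicate 2 (33.8%). The deleted PCH2 open reading frame (ORF) was left out of all comparisons of log ratios. A gene value was the mean of at least 2 probes that the array annotation places inside the ORF, and 5172 of 5538 ORFs had as many. Symbols came from the RefSeq gene table, and positions are those of the array annotation, whose genome build is not given in the sources used here.

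Differences between pch2 and wild type were tested with limma 3.58.1 in R 4.3.3 (with data.table in version 1.17.8 and statmod in version 1.5.0), with lmFit and eBayes, two-sided. One model held all 25 arrays, the 12 group means and 1 dye term. Levels of genes and lists, their SD and their values for single arrays are given after removal of this term. Such an SD is thus not the spread of the measured ratios. Genes were adjusted by Benjamini-Hochberg within each target and called at an adjusted p under 0.05. Groups of 2 or 3 arrays share 1 spread per feature in this model, and the number of arrays limits the precision of every value. The tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The 10 kb windows around the rDNA, and the tests named as such below, were chosen after the data were seen.

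The 21 lists were fitted together and adjusted over all 126 pairs of list and target. By position they were the left and right 50 kb flanks of the ribosomal DNA (rDNA) on chromosome XII, both flanks together, 10 kb on either side of the centromeres, and chromosome ends at 0 to 20 kb and at 20 to 110 kb. Further position lists were chromosomes I, III and VI, the silent mating-type loci HML and HMR, convergent, divergent and tandem intergenic regions, ORFs, and 500 bp upstream of hotspot genes. Gene lists covered meiotic break hotspots, early meiotic genes, middle sporulation genes, acetate use, glycolysis, histones, ribosomal proteins and the subtelomeric COS family. The rDNA borders are what the study itself concerns, so a change there is not independent evidence. PAU genes, the rDNA repeats, tRNA genes, transposon sequences and replication origins were planned as lists and were not analysed here. Of the fixed genes, HED1, HTA1, HTA2, HHF1 and HHF2 had no probe inside the ORF.

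Genes were named by rule: per target, the called genes with the largest rises and falls whose arrays did not overlap between strains after removal of the dye term, 8 of each for Hop1 and 4 of each otherwise, at most 1 per 20 kb. From each fixed gene list the called members, up to 4, were named, or else the 2 with the largest absolute change over all targets. The genes of the precipitated proteins, the 5 highest genes of each target in wild type (again at most 1 per 20 kb) and the 4 largest Hop1 changes in each rDNA flank were named as well, and PCH2 itself always.

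The mean of each chromosome was correlated with log10 of its length over the 16 chromosomes, with Pearson's r and two-sided permutation tests of 100000 resamples. A second coefficient computed for these relations did not pass for Mer2 and Mre11 in wild type or for the differences of Rec114 and H3, which passed by r, and is not reported here. PCH2 input signal was compared between strains by the same kind of test. Profiles of targets were correlated over 1 kb bins without a p, since neighbouring bins are not independent. Slides were read from the scanner headers, and each list was also fitted with slide as a block and compared within slides that held both strains.

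The model was tested on simulated arrays with known changes added to 200 of 4612 genes. These were drawn around the fitted means with independent normal noise and 1 spread per gene for all targets. Real targets differ in noise and neighbouring genes are not independent, so the shares may not hold for the real arrays. For Hop1, 43.3% of changes of 0.5 on the log2 scale were recovered, 88.1% of changes of 1 and 100% of changes of 2, with 9 false calls. For Rec114 the shares were 44.8%, 95.5% and 100%, with 5 false calls. A Hop1 change of 0.3 over the rDNA flanks was called in 29% of 200 simulations, one of 0.6 in 100%, and an absent one in 0.5%. At least 1 other pair of list and target was falsely called in 15, 21 and 17 of the 200 simulations, in this order.

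Alternatives were normexp background correction with an offset of 50, loess within arrays, quantile normalization, scaling of arrays to a common spread within a target, only probes well above background on every array, no dye term, only the arrays of a target, a replicate block, slide as a block, leaving out each array in turn, which leaves an arm of 1 array assumed to vary like the others, medians of probes, single probes, 5 kb bins, a trended and robust variance, flanks of 20 and 100 kb, the authors' group means, trends without 20 kb at each chromosome end or without chromosome XII, and, for PCH2, the IP channel, normexp correction or each target left out. Further alternatives were chosen after seeing the data: the authors' replicate columns, the labelled dyes for all arrays, leaving out both arrays of disputed direction, keeping all marked spots, applying the marks of every array, only the 40743 probes of the authors' table, and trends without chromosome III. The planned filter on repeated sequence was not run, since no map of repeats was used here.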

Results

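Chromatin immunoprecipitation on tiling arrays (ChIP-chip) was used to map proteins of meiotic DNA double-strand break formation in wild-type yeast and in pch2 mutants, which lack the AAA+ ATPase Pch2. Hop1 is a structural protein of the meiotic chromosome axis, Rec114 and Mer2 are accessory factors of the break-forming enzyme, and Mre11 belongs to a complex needed to form and process breaks. H3K4me3 marks the start of active genes and histone H3 reports nucleosomes. Each of the 12 groups of target and strain held 2 arrays, and Rec114 in wild type held 3.

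Median signals per array lay between 1140 and 1490 for Hop1, Rec114, Mer2 and Mre11, with at least 94.6% of probes well above background in the weaker channel. The H3K4me3 arrays had medians of 814 to 975, and on the weakest of them 47% of probes were well above background. For H3 the lowest share was 63.8%. Probe profiles of replicates had r of 0.815 to 0.896 for Hop1, 0.843 to 0.900 for Rec114, 0.797 to 0.798 for Mer2, 0.601 to 0.753 for Mre11, 0.512 to 0.569 for H3K4me3 and 0.397 to 0.404 for H3. The direction of 2 arrays, Rec114 wild type replicate 2 and Mer2 pch2 replicate 2, is disputed between the labels and the authors' table. Values here follow the table, whose direction is also that of the other arrays of each target.

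The PCH2 gene itself was missing from the input DNA of the mutants. Over its 6 probes (chromosome II, 600752 to 602306) the centred log2 input signal was -4.44 ± 1.53 (SD, n = 12) in pch2 arrays and 0.06 ± 0.29 (SD, n = 13) in wild-type arrays. The difference of -4.50 had p = 1e-05 in a two-sided permutation test, the smallest p that its resamples can give. Its size depended on the processing, with -4.88 to -1.34 over 8 alternatives. All 12 mutant arrays, between -6.25 and -1.98, lay below all 13 wild-type arrays, between -0.50 and 0.48.

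In wild type, Hop1, Rec114, Mer2 and Mre11 were higher between convergent genes than between divergent genes, while H3K4me3 was lower there. The difference was 1.00 ± 0.12 for Hop1 (log2, SD, n = 2, limma adjusted p = 1e-07), 0.65 ± 0.07 for Rec114 (n = 3, limma adjusted p = 1.3e-06), 0.54 ± 0.07 for Mer2 (n = 2, limma adjusted p = 5.4e-05) and 0.28 ± 0.13 for Mre11 (n = 2, limma adjusted p = 0.0098). It was -0.61 ± 0.04 for H3K4me3 (n = 2, limma adjusted p = 1.7e-05) and 0.30 ± 0.24 for H3 (n = 2, limma adjusted p = 0.0066). The regions held 2084 convergent and 4618 divergent probes. ORFs were above intergenic regions for H3 (0.39), Hop1 (0.22) and Rec114 (0.18), with limma adjusted p of 1.3e-06, 0.00041 and 0.00038. The difference did not pass for Mer2 (0.0077), Mre11 (-0.08) or H3K4me3 (0.04).

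None of the 12 location differences changed in pch2 by the limma test. The smallest adjusted p was 0.30, for a Rec114 difference between ORFs and intergenic regions that was lower by -0.15. Unadjusted, 1 of the 12 had p under 0.05 (0.025). Under the labelled dyes the Rec114 location differences were 0.22 for convergent regions (adjusted p = 0.40) and 0.10 for ORFs (0.34), and for Mer2 0.54 (0.11) and 0.0077 (0.92), and none passed. Without both disputed arrays the Rec114 differences were 0.65 and 0.21, and both passed. Loess within arrays moved the difference between ORFs and intergenic regions to -0.0062 for Hop1 and 0.032 for Rec114 (adjusted p = 0.91 and 0.51), and with it Mre11 (-0.12, 0.046) and H3K4me3 (-0.13, 0.041) passed. In the authors' replicate columns that difference was 0.017 for Hop1 (0.46), and Mer2 (-0.063, 0.017), Mre11 (-0.097, 0.0012) and H3K4me3 (-0.059, 0.023) passed, while the marks of every array gave Mre11 -0.16 (0.0053). Convergent differences missed the limit for H3 with normexp (0.15, 0.18) and for Mre11 over bright probes (0.14, 0.085), and without wild type replicate 2 the convergent difference was 0.18 for Mre11 (adjusted p = 0.24) and, for H3, 0.12 (0.39).

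Among genes, named at most 1 per 20 kb, the highest wild-type levels of Hop1 were at SAW1 (chromosome I, 94841 to 95378), 2.71 ± 0.03 on the log2 scale, and NTG1 (chromosome I, 126960 to 127872), 2.63 ± 0.22 (SD, n = 2). RAD18 and TRX3 on chromosome III had 2.41 and 2.35, and TSR4 on chromosome XV 2.28. SAW1 was also the highest gene for Rec114 (2.60 ± 0.11, n = 3) and Mer2 (2.53 ± 0.21, n = 2). For Mer2, NTG1, RAD18, TSR4 and PES4 followed by this spacing rule with 2.00, 1.98, 1.97 and 1.93, with ranks of 3, 4, 5 and 6 over all genes. CTR86 (2.32) and CKB1 (2.26) were among the 5 named for Rec114 by this rule, with ranks of 5 and 7 over all genes. Leaving out both disputed arrays put SAW1 (2.65) for Rec114 below YOL162W (2.73), and the labelled dyes put it (0.93) below YOL162W (1.18) and CTR86 (1.00). The wild-type Mer2 values did not move, since the disputed Mer2 array is from pch2.

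Several of the highest ratios rested on dim probes, and all genes named here were again at most 1 per 20 kb. For Rec114 these were YOL162W (2.44, 50% of wild-type readings well above background) and ARR2 (2.42, 0%). For Mre11 they were ARR1 (2.58, 50%), REE1 (2.09, 0%), YOL163W (2.06, 0%), ENA5 (1.73, 83.3%) and MAL11 (1.71, 33.3%). Part of the signal behind these ratios was near background. The centred log2 input signal of ARR2, REE1, YOL163W and MAL11 was under -2 on every array, with means of -6.02, -5.15, -5.86 and -5.47. The deleted PCH2 gene had -4.44 in pch2 arrays, so the ratios of ARR2, REE1, YOL163W and MAL11 do not show occupancy. H3K4me3 was highest over PUP3 (2.13), HAB1 (2.03), ATP10 (2.02), MEI5 (1.99) and QRI5 (1.98), with 75%, 50%, 87.5%, 83.3% and 100% of wild-type readings well above background. For H3 the highest values were below 1, at SPC42 (0.95), ATG4 (0.93), MIF2 (0.92), PBR1 (0.90) and ECM31 (0.89).

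The profiles of the 4 break factors resembled one another in wild type, and that of H3K4me3 ran against those of Hop1, Rec114 and Mer2. Over 11467 bins of 1 kb, r was 0.878 between Hop1 and Rec114, 0.852 between Hop1 and Mer2, 0.869 between Rec114 and Mer2 and 0.844 between Mer2 and Mre11. Mre11 had 0.724 with Rec114 and 0.663 with Hop1. H3K4me3 had -0.343 with Hop1, -0.237 with Rec114 and -0.230 with Mer2, and -0.0885 with Mre11, about 1 spread of 0.0819 from 0. Replicates of 1 target gave 0.928 for Hop1, 0.913 for Rec114, 0.908 for Mer2, 0.751 for Mre11, 0.848 for H3K4me3 and 0.715 for H3 on the same bins. When the labelled dyes were used, Rec114 had 0.796 with Hop1, 0.754 with Mer2 and 0.597 with Mre11. Without both disputed arrays these were 0.869, 0.850 and 0.698.

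Short chromosomes carried more of the 4 break factors per probe in wild type and less H3 and H3K4me3. Chromosome I had the highest mean, 0.83 for Hop1, 0.73 for Rec114, 0.62 for Mer2 and 0.32 for Mre11, against -0.03, 0.04, 0.03 and 0.0026 on chromosome IV, the longest on the array. Over the 16 chromosomes, the mean correlated with log10 length with r = -0.860 for Hop1, -0.769 for Rec114, -0.790 for Mer2 and -0.755 for Mre11. The r was 0.841 for H3K4me3 and 0.891 for H3. The permutation p of these r were 3e-05, 0.00024, 0.00028, 0.00072, 8e-05 and 2e-05, and the adjusted p over 12 relations 0.00018, 0.00067, 0.00067, 0.0012, 0.00032 and 0.00018. Without chromosomes I and VI, r was -0.753 for Hop1, -0.483 for Rec114, -0.543 for Mer2, -0.449 for Mre11, 0.730 for H3K4me3 and 0.829 for H3. The relations of Rec114, Mer2 and Mre11 thus rest in part on those chromosomes, and chromosomes are not independent samples.

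**Figure D1:**
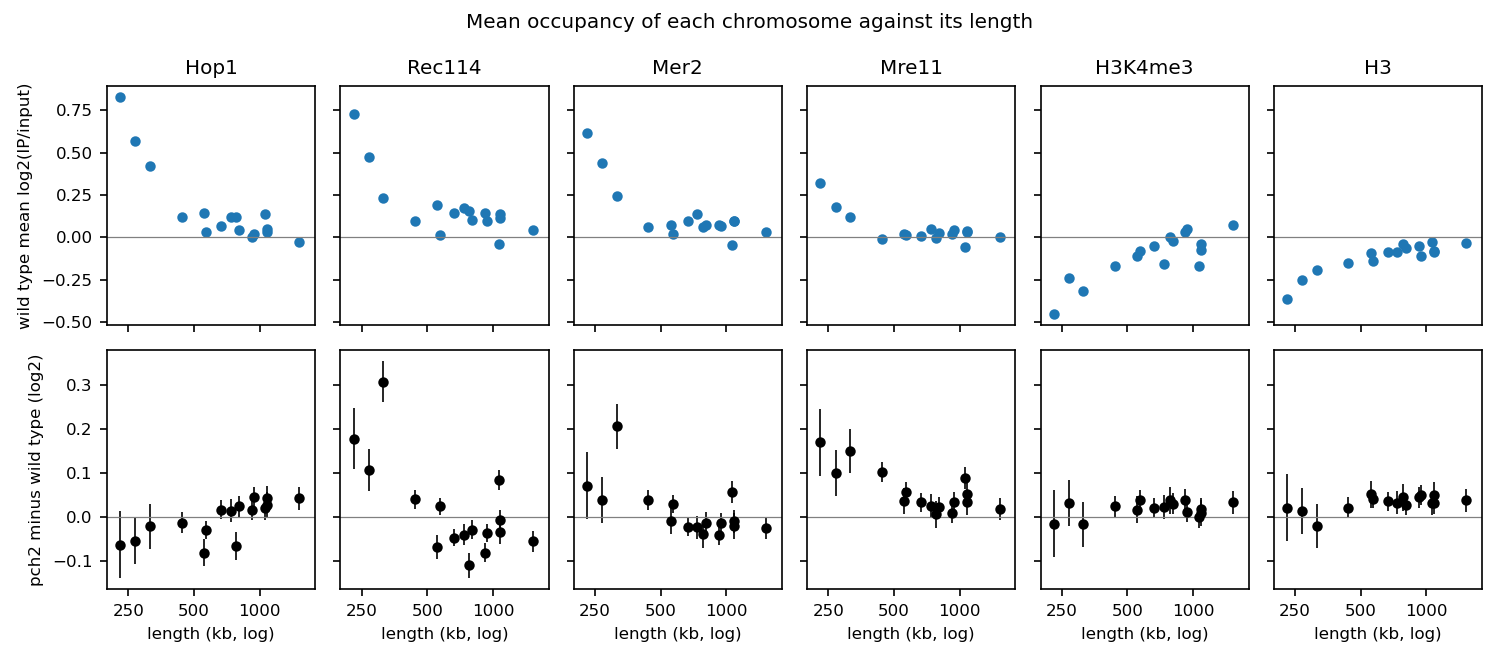
Mean log2(IP/input) of each chromosome in wild type (upper) and the difference pch2 minus wild type with its standard error (lower), against chromosome length in kb on a log axis, for the 6 targets. Points are the 16 chromosomes, and chromosome I, at the left, reaches 0.83 for Hop1 in wild type.

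Around the rDNA the strains differed in the break factors and not in the histone targets. Over the 307 probes within 50 kb of the repeats, Hop1 rose in pch2 by 0.33 ± 0.08 on the log2 scale (SE, limma adjusted p = 0.011), Rec114 by 0.54 ± 0.07 (0.00018), Mre11 by 0.41 ± 0.08 (0.0032) and Mer2 by 0.27 ± 0.08 (0.040). The means went from 0.17 to 0.50 for Hop1, from -0.46 to 0.08 for Rec114, from -0.26 to 0.15 for Mre11 and from -0.28 to -0.0079 for Mer2. For each of the 4 factors both pch2 arrays lay above every wild-type array. The values for H3K4me3 (-0.08 ± 0.08, adjusted p = 0.72) and H3 (-0.04 ± 0.08, adjusted p = 0.88) did not pass.

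With slide as a block the differences at the rDNA were 0.33 for Hop1 (limma adjusted p = 0.0035), 0.73 for Rec114 (0.0031), 0.47 for Mre11 (0.0035) and 0.24 for Mer2, which no longer passed (0.10). Within slides that held both strains they were 0.38 and 0.28 for Hop1, 0.67 for Rec114, 0.24 for Mer2 and 0.47 for Mre11. The remaining slides held 1 strain of these targets only. The Rec114 pair also differed in dye, with pch2 replicate 2 in Cy5 and wild type replicate 3 in Cy3. With slide as a block, here and below, the Rec114 values thus rest on the direction of wild type replicate 2, a disputed array. Hop1 arrays of both strains with the same number shared a slide, so a fit without 1 of them also sets slides against each other. Without Hop1 wild type replicate 1 the Hop1 difference was 0.20 (adjusted p = 0.23), and without Hop1 pch2 replicate 2 it was 0.26 (0.11). Mer2 lost the call without any 1 of its 4 arrays, with values of 0.23 (wild type replicate 1), 0.31 (wild type replicate 2), 0.27 (pch2 replicate 1) and 0.27 (pch2 replicate 2) and adjusted p of 0.25, 0.074, 0.17 and 0.15.

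With the labelled dyes the flank differences were 0.26 for Rec114 and 0.28 for Mer2, neither of which passed (limma adjusted p = 1 for both). In that fit the Hop1 and Mre11 values stayed at 0.33 and 0.41 and did not pass either, since all targets share 1 spread in the model, and the standard error for Hop1 grew from 0.08 to 0.22. Without both disputed arrays Rec114 had 0.56 (adjusted p = 0.0018) and Mer2 0.28 (0.17). Over the 98 flank probes well above background on every array the values were 0.32 for Hop1, 0.47 for Rec114, 0.22 for Mer2 and 0.43 for Mre11, with standard errors of 0.15 to 0.17, and none passed. Mer2 also missed the limit with normexp (0.29, adjusted p = 0.12) and loess (0.23, 0.078), and Mre11 when only its own arrays were fitted (0.41, 0.078).

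**Figure D2:**
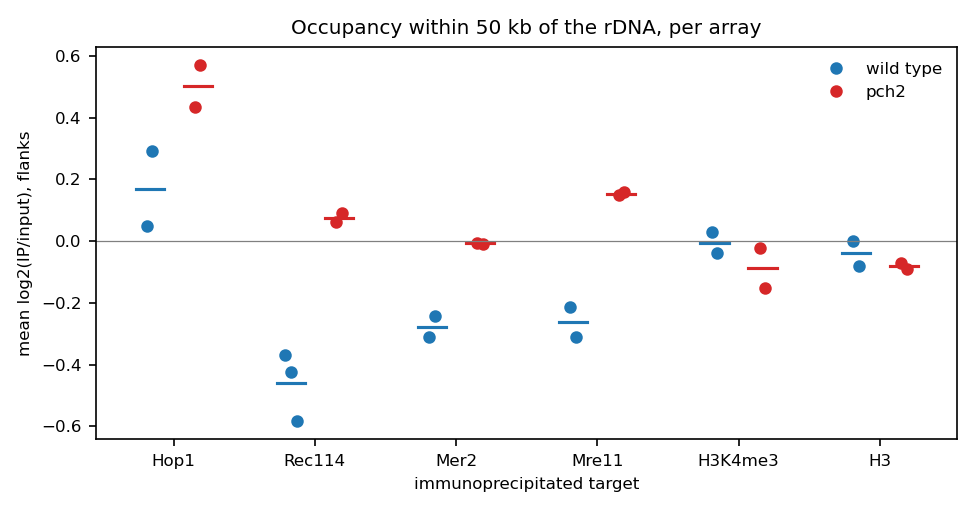
Mean log2(IP/input) within 50 kb of the rDNA for each array (points), with the group mean (bars), for 6 targets in wild type and pch2. The fitted dye term was removed from each value. Both pch2 arrays of Hop1, at 0.43 and 0.57, lie above both wild-type arrays, at 0.05 and 0.29.

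The rise was seen on both sides of the repeats. In the left flank (177 probes) it was 0.26 for Hop1, 0.50 for Rec114, 0.28 for Mer2 and 0.37 for Mre11, with limma adjusted p of 0.026, 0.00018, 0.014 and 0.0032. In the right flank (130 probes) it was 0.42 for Hop1, 0.58 for Rec114 and 0.47 for Mre11, with adjusted p of 0.0081, 0.00037 and 0.0044. Mer2 in the right flank had 0.25 and did not pass (0.14). Each flank lost the Hop1 call without Hop1 wild type replicate 1 (left 0.15, right 0.27) or without Hop1 pch2 replicate 2 (0.20 and 0.33). The left Mer2 call was lost without wild type replicate 1 (0.23), pch2 replicate 1 (0.28) or pch2 replicate 2 (0.29), and the right Mre11 call without wild type replicate 2 (0.38). With slide as a block the left Mer2 value of 0.24 did not pass (adjusted p = 0.10). Without both disputed arrays Rec114 passed on the left (0.52) and the right (0.60), while on the left Mer2 (0.29, adjusted p = 0.085) and Hop1 (0.26, 0.056) did not. Under the labelled dyes Rec114 had 0.22 and 0.30 and Mer2 0.30 and 0.26, and no target passed on either side (adjusted p = 1 for all).

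For Hop1 the change was largest within 20 kb of the repeats, and windows farther out passed for Rec114 and Mre11. The windows of 10 kb used here were chosen after the data were seen. Hop1 differed by 0.55 in the first 10 kb on the left (limma adjusted p = 0.000588). On the right it differed by 0.66 at 10 to 20 kb (0.000781), where the first 10 kb held too few probes. Hop1 passed in 2 windows on the left, out to 20 kb, and in 3 on the right, out to 40 kb. Rec114 passed in 8 windows on the left, the farthest ending at 90 kb, and in 9 on the right, out to 100 kb, with values of 0.26 to 0.78. Mre11 passed in 6 windows on the left, the farthest ending at 90 kb, and in 4 on the right, out to 50 kb, with values of 0.26 to 0.52. Mer2 passed within 20 kb on both sides, with values of 0.32 to 0.39. By the labelled dyes no window passed for any target. Leaving out both disputed arrays left Rec114 with 7 windows on the left and 8 on the right, and Mer2 with 1 and 0. Differences in reach were not tested.

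**Figure D3:**
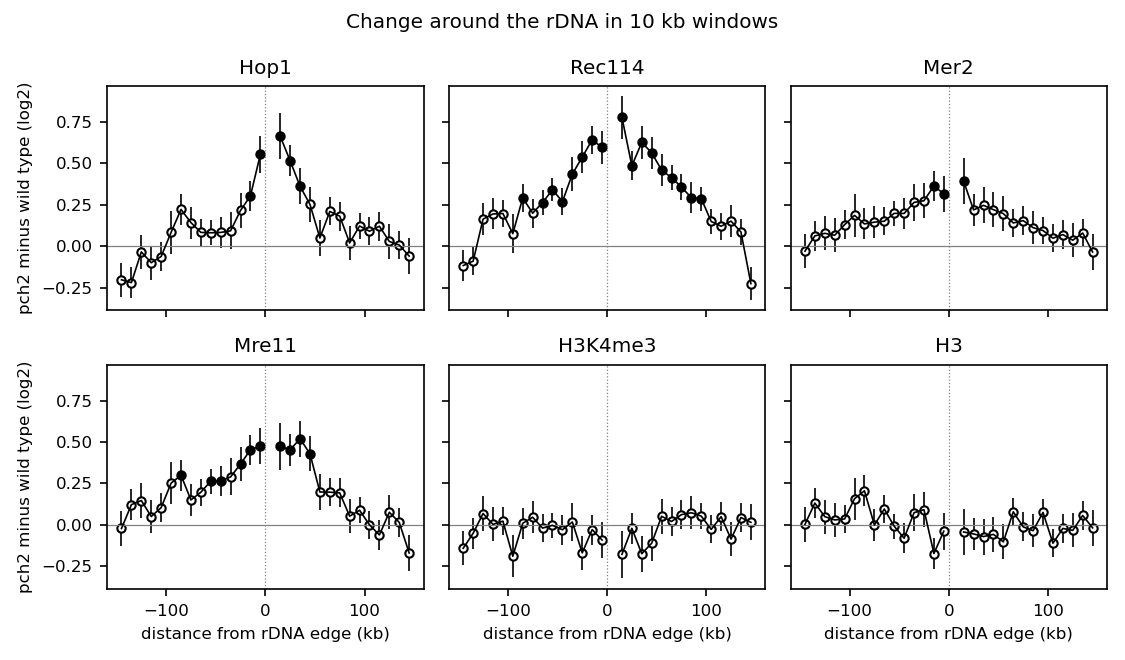
Difference pch2 minus wild type in log2(IP/input) with its standard error in 10 kb windows on either side of the rDNA (distance in kb, left negative), for 6 targets. Filled points passed at an adjusted p under 0.05, and the Hop1 values reach 0.55 on the left and 0.66 on the right.

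The change in Hop1 at the flanks differed from that in the histone targets. It exceeded the H3 change by 0.37 ± 0.12 (SE, limma adjusted p = 0.013) and the H3K4me3 change by 0.41 ± 0.12 (0.013). Against the other break factors the difference did not pass: -0.20 with Rec114 (adjusted p = 0.14), 0.06 with Mer2 (0.59) and -0.08 with Mre11 (0.59). In the left flank alone Hop1 changed less than Rec114, by -0.24 (adjusted p = 0.044), which missed the limit without both disputed arrays (-0.26, 0.057) and without Hop1 wild type replicate 2 (-0.12), Hop1 pch2 replicate 1 (-0.18), Hop1 pch2 replicate 2 (-0.30), Rec114 wild type replicate 3 (-0.18), Rec114 pch2 replicate 1 (-0.26) or Rec114 pch2 replicate 2 (-0.22). Those 2 arrays left out, the differences from H3 and H3K4me3 over both flanks passed (adjusted p = 0.024 for both), and by the labelled dyes no difference between targets passed. The difference from H3 did not pass without Hop1 wild type replicate 1 (0.24, adjusted p = 0.080), Hop1 pch2 replicate 2 (0.30, 0.066) or H3 wild type replicate 1 (0.33, 0.063), and that from H3K4me3 did not without Hop1 wild type replicate 1 (0.28, 0.06) or Hop1 pch2 replicate 2 (0.34, 0.066). Without Hop1 wild type replicate 1 the difference from Rec114 over both flanks passed (-0.33, 0.039).

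Single genes of the flanks followed the same direction. For Hop1, 39 of 43 flank ORFs were above 0, none passed over all genes, and 6 passed when adjusted over the list alone. For Rec114 all 43 were above 0, 10 passed over all genes and 29 adjusted over the list alone. For Mre11 all 44 were above 0, none passed over all genes and 18 passed adjusted over the list alone. For Mer2 all 44 were above 0 and none passed by either count. With both disputed arrays left out 1 gene passed for Rec114 over all genes and 25 over the list alone, and by the labelled dyes none did, with 34 above 0 for Rec114 and 43 for Mer2. The largest Hop1 values on the right were at UPS2 (chromosome XII, 499557 to 500266), a mitochondrial lipid regulator, with 0.82 ± 0.15 (SE, limma adjusted p = 0.103), PUS5 (0.66, 0.294), RPS31 (0.56, 0.90) and SHH4 (0.50, 0.90). On the left they were at YLR152C (0.58, 0.252), PCD1 (0.53, 0.90), RRN5 (0.48, 0.90) and GID11 (0.46, 0.90). Single arrays moved these Hop1 values. Without wild type replicate 1 RRN5 had 0.05, GID11 0.28 and PCD1 0.33, and without wild type replicate 2 RRN5 had 0.92. Without pch2 replicate 1 RPS31 had 0.23 and SHH4 0.78, and without pch2 replicate 2 they had 0.88 and 0.23.

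Centromeres also gained break factors in pch2. Within 10 kb of the centromeres (1150 probes) Hop1 rose by 0.24 ± 0.06 (SE, limma adjusted p = 0.010), Rec114 by 0.24 ± 0.05 (0.0069) and Mre11 by 0.18 ± 0.06 (0.044). Mer2 had 0.13 (adjusted p = 0.20), H3K4me3 -0.01 (0.96) and H3 -0.03 (0.91), none of which passed. With slide as a block the values were 0.24 for Hop1 (adjusted p = 0.016), 0.40 for Rec114 (0.036) and 0.19 for Mre11, which did not pass (0.19). Within slides they were 0.28 and 0.19 for Hop1, 0.36 for Rec114 and 0.19 for Mre11. The Hop1 call was lost without wild type replicate 1 (0.22, adjusted p = 0.084) or pch2 replicate 1 (0.20, 0.072), and the Mre11 call without any 1 of its 4 arrays (0.17 to 0.20, adjusted p = 0.11 to 0.21). By the labelled dyes Rec114 had 0.15 and did not pass (adjusted p = 1), and without both disputed arrays 0.26 (0.018).

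Among the other position lists, Rec114 rose over the short chromosomes I, III and VI by 0.20 ± 0.06 (SE, limma adjusted p = 0.027) and over the 3 probes of HML and HMR, the silent mating-type loci, by 0.62 ± 0.14 (0.0077). With slide as a block the first was 0.39 (adjusted p = 0.060) and the second 1.14 (0.016). Within the slide that held both strains the short chromosomes had 0.30. The short-chromosome call was lost without Rec114 wild type replicate 2 (0.18, adjusted p = 0.11), wild type replicate 3 (0.20, 0.052) or pch2 replicate 2 (0.11, 0.42), and the HML and HMR call without pch2 replicate 2 (0.42, 0.17). By the labels these values were 0.47 and 0.64 (adjusted p = 1 for both), and without both disputed arrays 0.18 (0.15) and 0.67 (0.021). Both lists overlap, since HML and HMR lie on chromosome III. That chromosome rose more in Rec114 (0.31) than I (0.18) or VI (0.11). Its left end, described below, holds both HML and CHA1. The HML and HMR call is therefore not separate from the rise there, and what its 3 probes add was not tested. Chromosome ends up to 20 kb had 0.23 for Rec114 (adjusted p = 0.077) and 0.27 for Mre11 (0.051), and ends from 20 to 110 kb had -0.08 for Hop1 (0.28). Convergent, divergent and tandem intergenic regions, ORFs and the 26 probes upstream of hotspot genes did not pass for any target. In all, 16 of 126 pairs of list and target passed, each of them higher in pch2, and 27 had an unadjusted p under 0.05.

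No gene list passed as a group in the model of all arrays by limma. With slide as a block the acetate-use genes passed for Mre11, with 0.38 (adjusted p = 0.013) against 0.25 (0.22) without the block. CHA1, a serine and threonine deaminase gene on chromosome III (15949 to 16761) known as a break hotspot, was the only listed gene that rose over all genes, by 1.08 ± 0.18 in Rec114 (SE, limma adjusted p = 0.00648). Of 14 measured hotspot genes, 1 passed for Rec114 over all genes and 2 adjusted over the list alone, and without both disputed arrays 0 and 1. By the labelled dyes no listed gene passed for Rec114 by either count. For Mre11, 3 of 15 acetate-use genes and 1 of 3 histone genes passed adjusted over the list alone, and for Rec114 1 of 3 histone genes. Early meiotic, middle sporulation, glycolytic, ribosomal protein and COS genes had none by either count for any target, except 1 of 15 glycolytic genes that was lower in H3K4me3 adjusted over the list alone. This was PDC1, whose H3K4me3 signal lay near background (10% of wild-type readings well above it).

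Listed genes with the largest values included ACS1 (0.55) and ALD4 (0.54) in Mre11 among acetate-use genes, and MEI4 in H3 (0.41) and REC107 in Mre11 (0.38) among early meiotic genes. PGK1 had 0.53 in Mre11 and PDC1 -0.49 in H3K4me3, from probes of which 10% of wild-type readings were well above background, HTB2 0.57 in Mre11 and HTB1 0.30 in Rec114, DIT2 -0.46 in Rec114 and SMK1 0.45 in Mre11. RPS30A had 0.93 in Mre11 and RPL20B 0.83 in H3K4me3 (25% well above background), and COS10 had 0.39 in H3K4me3 (37.5%) and COS9 -0.30 in Mre11. None of these passed over all genes, and RPL20B passed only without H3K4me3 wild type replicate 1 (1.503, limma adjusted p = 0.0311), with 0.15 when wild type replicate 2 was left out. Leaving out single arrays moved PGK1 between 0.21 and 0.85 (Mre11 wild type replicates 2 and 1), MEI4 between 0.14 and 0.67 (H3 pch2 replicates 2 and 1), ACS1 to 0.32 (Mre11 wild type replicate 2), RPS30A to 0.59 (Mre11 pch2 replicate 1), COS9 to -0.18 (Mre11 pch2 replicate 2) and HTB1 to 0.18 (Rec114 wild type replicate 3). The genes of the precipitated proteins did not pass for their own target, with 0.26 for HOP1 in Hop1, 0.20 for REC114 in Rec114, -0.03 for REC107 (the gene of Mer2) in Mer2 and -0.16 for MRE11 in Mre11. HOP1 had -0.02 without Hop1 pch2 replicate 1 and 0.53 without pch2 replicate 2, REC114 0.13 without Rec114 pch2 replicate 2, and REC107 changed sign with single Mer2 arrays left out (-0.09 without pch2 replicate 1, 0.04 without pch2 replicate 2). For MRE11 the extremes were -0.27 and -0.05, without Mre11 wild type replicates 1 and 2.

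Over all genes, Rec114 was the target with called changes. Of 5047 genes, 29 rose and 29 fell in pch2, and 670 had an unadjusted p under 0.05 where chance gives 252. Of the 29 that rose, 18 lay on the left end of chromosome III, between 15949 and 61098, 10 in the rDNA flanks and 1 on chromosome V. With at most 1 gene named per 20 kb, the largest rises were at PBN1 (chromosome III, 34294 to 35276), an endoplasmic reticulum mannosyltransferase component, with 1.32 ± 0.16 (SE, limma adjusted p = 0.000482), PUS5 (0.95, 0.00153), PEP3 (0.79, 0.00663) and ATG22 (0.78, 0.0287), while CHA1, within 20 kb of PBN1, had 1.08. The genes that fell were spread over 10 chromosomes, with 5 each on IV and XIV. Under the same rule the largest falls were at MON2 (-0.91, adjusted p = 0.0067), CCH1, a calcium channel gene (-0.88, 0.00326), NAM2 (-0.77, 0.0402) and URA2 (-0.76, 0.0202), genes with high Rec114 in wild type (1.35, 0.97, 1.17 and 1.24). All 29 genes that rose were also above 0 in Mer2, with or without both disputed arrays, but 15 of them by the labelled dyes. In Mre11 28 were above 0, and in Hop1 22, with 13 of the 18 on chromosome III. Most of the 29 are neighbours on the left end of chromosome III or in the rDNA flanks, so they are not independent counts.

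The Rec114 counts moved with single arrays and with scaling. Without pch2 replicate 2 no gene passed (543 at an unadjusted p under 0.05), without pch2 replicate 1 14 passed, all higher, without wild type replicate 3 12 (10 higher), without wild type replicate 2 24 (14 higher), and without both disputed arrays 5 (4 higher). With the labelled dyes none passed (61 at an unadjusted p under 0.05), and with slide as a block none passed (245). Normexp correction gave 37 higher and 132 lower, loess 16 and 1, quantile normalization 82 and 81, and scaling of spread 66 and 54. Of the named genes, PBN1, PUS5 and CCH1 passed without both disputed arrays (1.27, 0.95 and -0.95), and PEP3 (0.78), ATG22 (0.70), MON2 (-0.93), NAM2 (-0.84), URA2 (-0.84) and CHA1 (1.00) did not. The labelled dyes gave them values of 1.41, 0.68, -0.33, 0.54, 1.44, -0.03, -0.09, -0.04 and 0.75 in this order, and none passed. Without pch2 replicate 2 none of the 9 passed, without pch2 replicate 1 ATG22 (0.96), MON2 (-0.83), CCH1 (-0.84), NAM2 (-0.67) and URA2 (-0.63) did not, and without wild type replicate 3 ATG22 (0.72), NAM2 (-0.57) and URA2 (-0.59) did not. ATG22 (0.71) and NAM2 (-0.84) also missed the limit without wild type replicate 2.

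No gene passed for the other targets in limma. For Hop1, 251 of 4918 genes had an unadjusted p under 0.05 (chance gives 246), for Mer2 55 of 5159 (258), for Mre11 677 of 5151 (258), for H3K4me3 271 of 5167 (258) and for H3 106 of 4870 (244). The median standard error of a gene was 0.166 for Hop1 and 0.167 for Mre11. The labelled dyes gave Mer2 44 such genes and without both disputed arrays 20, none of which passed. Without Mre11 wild type replicate 2, 27 genes passed for Mre11, without wild type replicate 1 1 gene and without pch2 replicate 1 3 genes. Without H3K4me3 wild type replicate 1, 52 genes passed for H3K4me3 and without pch2 replicate 1 5, and without H3 pch2 replicate 1, 22 passed for H3. Quantile normalization gave 665 genes for Mre11 and 6 for Mer2, and a fit of the Mer2 arrays alone gave 865 for Mer2.

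H3K4me3 relative to H3, a measure of methylation per nucleosome, passed at none of 4866 genes (limma, 153 at an unadjusted p under 0.05 where chance gives 243, smallest adjusted p 0.958). Without H3K4me3 wild type replicate 1, 5 genes passed, without H3 wild type replicate 1 1 gene, and without H3 pch2 replicate 1 11 genes.

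Over chromosomes, which are not independent samples, the change in pch2 went with length positively for Hop1 and negatively for the other break factors. Across the 16 chromosomes the difference pch2 minus wild type correlated with log10 length with r = 0.725 for Hop1, -0.697 for Rec114, -0.637 for Mer2 and -0.784 for Mre11, with permutation p of 0.0017, 0.0029, 0.006 and 0.00058 and adjusted p over the 12 relations of 0.0025, 0.0039, 0.0069 and 0.0012. For H3, r was 0.641 (permutation p = 0.0063, adjusted 0.0069) and for H3K4me3 0.379 (permutation p = 0.15). Without chromosomes I and VI r was 0.611, -0.590, -0.663, -0.647, 0.620 and 0.306 for Hop1, Rec114, Mer2, Mre11, H3 and H3K4me3. When each array gave 1 slope and the strains were compared, the change passed for Rec114 (-0.32 ± 0.08 per log10 unit of length, SE, limma adjusted p = 0.004) and not for Hop1 (0.13, 0.20), Mer2 (-0.17, 0.13), Mre11 (-0.16, 0.13), H3 (0.05, 0.68) or H3K4me3 (0.03, 0.74). The Rec114 slope change fell short without pch2 replicate 2, at -0.18 (adjusted p = 0.078). Without both disputed arrays the Rec114 slope changed by -0.28 (adjusted p = 0.039) and the Mer2 slope by -0.19 (0.19), and under the labelled dyes by -0.67 (0.48) and 0.54 (0.57). Of the chromosomes, III had the highest Rec114 difference, 0.31 ± 0.05 (SE), over a mean of 0.23 in wild type, and 0.29 without both disputed arrays, again the highest. By the labelled dyes it had 0.44, below chromosome I with 0.63.

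The Hop1 relation with length depended on the scaling. It was -0.0383 with loess and 0.138 with arrays scaled to a common spread, neither of which passed. Normexp gave 0.551 for H3K4me3, which passed (adjusted p = 0.029), and 0.297 for H3 (0.26), loess gave -0.668 for H3K4me3 (0.0052), and bright probes gave 0.461 for H3 (0.076). For Mer2 the r was 0.785 with the labelled dyes and -0.677 without both disputed arrays, and for Rec114 -0.855 and -0.659. Without H3 pch2 replicate 1 the r for H3 was -0.321 (permutation p = 0.23) and without H3 wild type replicate 2 it was 0.475 (0.064). Mer2 had -0.485 without wild type replicate 1 (0.053). For H3K4me3 it was -0.307 without wild type replicate 1 and 0.508 (0.043) without wild type replicate 2.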

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

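The tests for lower IP contrast were planned; the tests of slides, input DNA, dye direction and a change shared with Hop1, the region on chromosome III and the differences between targets there and in slope were chosen after the results were seen. Differences between targets in the pch2 effect brought up 7 results, each by a limma test of the difference itself. No group had enough arrays to look for a single array far from the others.

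At the rDNA flanks the Hop1 change exceeded that of H3K4me3 by 0.41 and that of H3 by 0.37 (limma adjusted p = 0.013 for both). The difference from H3 lay between 0.24 and 0.51 with single arrays left out and missed the limit without Hop1 wild type replicate 1 (0.24), Hop1 pch2 replicate 2 (0.30) or H3 wild type replicate 1 (0.33). The left end of chromosome III, the first 80 kb with 257 probes, was chosen because 18 of the 29 genes with a called Rec114 rise lie there, so its Rec114 values are not a separate test of that rise. In this region the Hop1 change was below that of Rec114 by -0.72 (limma adjusted p = 0.00047), a difference that the choice of region favoured. The Hop1 change was below that of Mer2 by -0.41 (0.029). The difference from Mre11 there, -0.22, did not pass (0.25). The slope of signal on log10 chromosome length changed by 0.45 more for Hop1 than for Rec114 (limma adjusted p = 0.0053), by 0.30 more than for Mer2 (0.038) and by 0.30 more than for Mre11 (0.038). When both disputed arrays were left out the slope difference passed for Rec114 (0.41, 0.025) and missed the limit for Mer2 (0.32, 0.058) and Mre11 (0.30, 0.058). By the labelled dyes none of the 7 differences passed. Single arrays left out ended 4 of the calls besides that against H3. These were the flank difference from H3K4me3 (without Hop1 wild type replicate 1, 0.28, or pch2 replicate 2, 0.34), the Mer2 difference on chromosome III (without Hop1 wild type replicate 1, -0.37, Hop1 pch2 replicate 1, -0.36, Mer2 wild type replicate 1, -0.33, or Mer2 pch2 replicate 1, -0.38) and the slope differences from Mer2 (without Hop1 wild type replicate 1, 0.30, or 2, 0.29, Hop1 pch2 replicate 1, 0.24, Mer2 wild type replicate 1, 0.23, or Mer2 pch2 replicate 1, 0.27) and from Mre11 (without Hop1 wild type replicate 1, 0.30, or 2, 0.29, Hop1 pch2 replicate 1, 0.24, Mre11 wild type replicate 1, 0.28, or 2, 0.32, or Mre11 pch2 replicate 1, 0.20).

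The first pattern weighed was the rDNA-flank rise in pch2 for Hop1, Rec114, Mer2 and Mre11. For Hop1, differences between arrays of the same slide (0.38 and 0.28) and the test with slide as a block argue against slides as the whole cause. Rec114 (0.73) and Mre11 (0.47) also passed with slide as a block. Each rests on a single same-slide pair, whose spread cannot be measured, so the argument is weaker there. The Rec114 pair also differed in dye, and the dye term of its block fit came from a slide that holds the disputed Rec114 array. Its block value thus hangs on the direction of that array, and the argument is weakest for Rec114. No Hop1 or Mre11 array is disputed, and Rec114 passed without both disputed arrays (0.56, limma adjusted p = 0.0018). The Mer2 change moved by at most 0.014 between 0.27 ± 0.08 as used, 0.28 ± 0.22 with the labelled dyes and 0.28 ± 0.11 without both arrays (SE), its call lost as the spread grew. The disputed Mer2 array lay near 0 at the flanks (-0.01), so turning it could hardly move the change, and the labelled dyes are no separate test. For all 4 factors these values argue against dye direction. For all 4 factors the flank change exceeded that expected from the wild-type level by at least 2.85 standard errors. This argues against lower IP contrast as the whole cause. The standard errors are those of the flank change alone, without the scatter of the fit over other windows. They therefore do not set the flanks apart from those windows. The largest fall in the input signal, -0.074 in Hop1, argues against a loss of input signal as the whole cause. For Mer2 the same-slide difference of 0.24 did not pass with slide as a block (limma adjusted p = 0.10), so slide cannot be told apart from strain there. Extraction protocol and scanner went in part with strain for Mer2 and Mre11 and were not tested, though their same-slide pairs shared both. Also open are the background of the Myc antibody for Rec114, Mer2 and Mre11 and, for all 4 factors, any other difference between the strains. The absence of Pch2 may raise these factors at the rDNA borders, a hypothesis for Hop1, Rec114 and Mre11 that rests on these same arrays.

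The second pattern was the chromosome III left-end rise in pch2 for Rec114 and Mer2. Rec114 went from 0.20 to 1.00, a change of 0.80 ± 0.09 (SE, limma adjusted p = 1.9e-06), and Mer2 changed by 0.49 ± 0.10 (0.00069), with slide-block values of 1.16 (2.7e-05) and 0.44 (0.0016). The region was chosen for its Rec114 rises, so the Rec114 p, adjusted over the 6 targets only, are not those of a separate test. Without both disputed arrays Rec114 changed by 0.78 and Mer2 by 0.52, the latter from 1 pch2 array, replicate 1. The slide-block value of Mer2 rests on that same array in a single same-slide pair, so these are not separate results. The slide-block value of Rec114 rests on the direction of its disputed array. By the labelled dyes Mer2 had -0.21 (limma adjusted p = 0.96) and Rec114 0.91 (0.04). The residuals from the wild-type level were at least 5.01 standard errors above 0, the lowest in Mer2. These standard errors too leave out the scatter of the fit over other windows. For Mer2, whose values did not define the region, the residual argues against lower contrast as the whole cause. Against dye direction there is only the 1 undisputed pch2 array of Mer2, so that argument is weak. For Rec114 they cannot decide, since the region was chosen on its values. The largest fall in the input signal was -0.055, in Rec114, which argues against a loss of input signal as the whole cause. The Hop1 change was below that of Mer2 by -0.44 without both disputed arrays and missed the limit (0.059), so a change shared with Hop1 stays open. A difference in sequence or structure of this region between the tagged strains, as well as the loss of Pch2, may lie behind it, and neither was tested.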

How the results depend on the processing

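The authors' replicate columns, the labelled dyes, leaving out both disputed arrays, both changes to the marked spots, the probes of the authors' table, and for the trends the bright probes and chromosome III left out were chosen after seeing the data. The repeat filter was not run, and the authors' group means give no count of genes or lists. The cause of each change below was not tested unless stated.

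The higher Hop1, Rec114, Mer2 and Mre11 at the rDNA flanks kept its direction under all 19 alternatives, with 0.22 to 0.48 for Hop1, 0.26 to 0.73 for Rec114, 0.20 to 0.41 for Mer2 and 0.29 to 0.59 for Mre11. The calls held in 17, 17, 13 and 16 of them, with limma adjusted p reaching 1 for each. The PCH2 input difference held in 8 alternatives, from -4.88 to -1.34.

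Normexp correction gave 169 called genes for Rec114 (37 higher), 19 for Mre11 (1 higher) and 9 list calls, a Mer2 flank value of 0.29 (adjusted p = 0.12), an H3 convergent minus divergent difference of 0.15 (0.18), and change trends with length of 0.551 for H3K4me3, which passed, and 0.297 for H3, which did not.

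Loess gave 17 genes for Rec114 (16 higher) and 1 for Mre11, and 0.23 for Mer2 at the flanks (0.078). Its ORF minus intergenic differences were -0.0062 for Hop1, 0.032 for Rec114, -0.12 for Mre11 (0.046) and -0.13 for H3K4me3 (0.041). Change trends were -0.0383 for Hop1 and -0.668 for H3K4me3, and profile correlations 0.861 for Hop1 with Rec114, -0.229 for Hop1 with H3K4me3 and -0.184 for Rec114 with H3K4me3.

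Quantile normalization gave 163 genes for Rec114, 6 for Mer2, 665 for Mre11 (356 higher) and 27 list calls. Scaling to a common spread gave 3 genes for Hop1, 120 for Rec114 and 3 for Mre11, and a Hop1 change trend of 0.138.

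Only bright probes gave 7 genes for Rec114 of 2360 tested and 0 list calls in limma (12 at an unadjusted p under 0.05), with flank values of 0.32 for Hop1, 0.47 for Rec114, 0.22 for Mer2, 0.43 for Mre11 and 0.32 for Hop1 minus H3. Fewer probes gave these a standard error of 0.17, or 0.15 for Rec114. The Mre11 convergent minus divergent difference was 0.14 and the H3 change trend 0.461.

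Without a dye term 34 genes were called for Rec114. With only the arrays of the target there were 11 for Rec114, 865 for Mer2 (234 higher) and 22 for Mre11, and Mre11 kept values of 0.41 at the flanks (0.078) and 0.28 for convergent minus divergent regions (0.05), now from fewer arrays. The replicate block gave 13 genes for Rec114 (11 higher), 0.33 for Hop1 at the flanks and 18 list calls. Arrays of both strains with the same number shared a slide for Hop1, H3K4me3 and H3 and, as replicate 2, for Mre11, and no day of culture is given. Slide as a block gave 0 genes for Rec114 (245 at an unadjusted p under 0.05), 1 for Mre11 and 0.24 for Mer2 at the flanks (0.10). For wild-type levels slide entered as a random block.

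Medians of probes gave 36 genes for Rec114. Single probes gave 0 called probes for Rec114 (1515 at an unadjusted p under 0.05), 1 for Mre11 and 8 for H3K4me3, and correlations of 0.865 for Hop1 with Rec114, -0.269 for Hop1 with H3K4me3, 0.624 for Rec114 with Mre11, 0.768 for Mer2 with Mre11 and 0.192 for H3K4me3 with H3. Bins of 5 kb gave 5 for Hop1, 210 for Rec114 (72 higher), 1 for Mer2, 1 for H3K4me3 and 1 for H3K4me3 over H3, and correlations with H3K4me3 of -0.287 for Hop1, -0.133 for Rec114 and -0.146 for Mer2. Flanks of 100 kb gave 0.22 for Hop1 minus H3 (0.076).

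The authors' group means gave -0.27 for H3K4me3 convergent minus divergent, and ORF minus intergenic differences of 0.017 for Hop1, 0.056 for Rec114, -0.063 for Mer2, -0.059 for H3K4me3 and 0.21 for H3. Their replicate columns gave 273 genes for Rec114 (67 higher), 13 for Mre11, and ORF minus intergenic differences of 0.017 for Hop1 (0.46), -0.063 for Mer2 (0.017), -0.097 for Mre11 (0.0012) and -0.059 for H3K4me3 (0.023).

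The labelled dyes gave 0 genes for Rec114 in limma (61 at an unadjusted p under 0.05) and 0 list calls (3). Flank values were 0.33 for Hop1, 0.26 for Rec114, 0.28 for Mer2, 0.41 for Mre11 and 0.37 for Hop1 minus H3, none of which passed, and the Hop1 standard error grew from 0.08 to 0.22. Convergent minus divergent differences were 0.22 for Rec114, 0.54 for Mer2, 0.28 for Mre11, -0.61 for H3K4me3 and 0.30 for H3, and ORF minus intergenic differences 0.22 for Hop1 and 0.10 for Rec114, none of which passed. The Mer2 change trend was 0.785, and correlations of Rec114 were 0.796 with Hop1, 0.754 with Mer2, 0.597 with Mre11 and -0.278 with H3K4me3. Leaving out both disputed arrays gave 5 genes for Rec114 and 0.28 for Mer2 at the flanks (0.17). Keeping marked spots gave 2 genes for Mre11. Applying every mark gave 32 for Rec114 and an Mre11 ORF minus intergenic difference of -0.16 (0.0053).

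Leaving out single arrays gave 0 to 74 genes for Rec114, with 0 without pch2 replicate 2 (543 at an unadjusted p under 0.05), 12 without wild type replicate 3, 14 without pch2 replicate 1 and 24 without wild type replicate 2. It gave 0 to 27 for Mre11 (27 without wild type replicate 2, 3 without pch2 replicate 1, 1 without wild type replicate 1), 0 to 52 for H3K4me3 (52 without wild type replicate 1, 5 without pch2 replicate 1), 0 to 22 for H3 (22 without pch2 replicate 1) and 0 to 11 for H3K4me3 over H3 (11 without H3 pch2 replicate 1, 5 without H3K4me3 wild type replicate 1, 1 without H3 wild type replicate 1). Flank values ranged from 0.20 to 0.46 for Hop1 (0.20 without wild type replicate 1, 0.26 without pch2 replicate 2), from 0.23 to 0.31 for Mer2, whose call was lost each time, and from 0.24 to 0.51 for Hop1 minus H3 (0.24 without Hop1 wild type replicate 1, 0.30 without Hop1 pch2 replicate 2, 0.33 without H3 wild type replicate 1). Convergent minus divergent differences ranged from 0.18 to 0.37 for Mre11 (0.18 without wild type replicate 2) and from 0.12 to 0.48 for H3 (0.12 without wild type replicate 2).

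Signal over background limits H3K4me3 most, where 47% of probes were well above background on the weakest array, and 11343 probes were so on every array.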

Other observations

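All values of this part were chosen after the data were seen. In 593 windows of 20 kb, limma called 62 higher and 102 lower in pch2 for Rec114, 6 and 5 for Hop1, 7 and 1 for Mre11 and 2 and 0 for Mer2. It called none for H3K4me3 (16 at an unadjusted p under 0.05) or H3 (2). With the labelled dyes no window passed for any target, and without both disputed arrays 123 passed for Rec114, 6 for Hop1, 2 for Mre11 and 0 for Mer2. Across these windows, which are not independent, the changes correlated with r = 0.899 between Rec114 and Mer2, 0.745 between Rec114 and Mre11, 0.747 between Mer2 and Mre11, 0.543 between Hop1 and Rec114, 0.547 between Hop1 and Mre11 and 0.423 between Hop1 and Mer2. Leaving out both disputed arrays gave 0.857 between Rec114 and Mer2, 0.73 between Rec114 and Mre11, 0.778 between Mer2 and Mre11, 0.548 between Hop1 and Rec114 and 0.388 between Hop1 and Mer2, and the labelled dyes gave -0.724, 0.301, 0.187, 0.0109 and 0.193. With the wild-type level taken from 1 array and the change from the others, the change correlated with the level with a mean r of -0.431 for Hop1, -0.415 for Rec114, -0.26 for Mer2, -0.081 for Mre11, 0.263 for H3K4me3 and 0.157 for H3. Single splits reached -0.00109 for Mer2 and lay between -0.225 and 0.751 for H3K4me3.

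On the left end of chromosome III Mre11 changed by 0.29 (limma adjusted p = 0.024), with 0.17 when slide was a block (0.14), 0.22 without Mre11 wild type replicate 1 (0.22) and 0.24 without Mre11 pch2 replicate 1 (0.18). Hop1 (0.07), H3K4me3 (-0.02) and H3 (-0.09) did not pass there.

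Of 5172 genes, 8 had a centred log2 input signal under -2 on every array: YIR042C, MAL11, REE1, BDS1, YOL163W, SGE1, ARR2 and ARR3, with means of -6.02 (ARR2) to -4.04 (YIR042C). The input signal of URA3, over 3 probes, was 0.23 and 0.26 in wild type and 0.23 and 0.25 in pch2 for Rec114 and Mre11, and between 0.63 and 0.96 in the groups of the other 4 targets.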
